A study of Homo sapiens with 22 samples.

How the data were processed

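The series deposited 1 table of normalized expression for 22 human RNA-seq libraries, and all values below start from it. Per the labels, RNA was selected by its poly-A tail, prepared with the Illumina TruSeq RNA kit and sequenced on a HiSeq2000. The submitters' processing notes name CASAVA 1.8.2, TopHat, Cufflinks and DESeq, without versions for the last 3 and without saying what each did. They list the builds GRCh37 and mm9, the second being a mouse genome, although every library is labelled human. For the 4 T164A libraries mm9 alone is listed. How the authors normalized the values is not stated. The deposited unit is log2, on the scale of depth-adjusted counts: 2 to the power of the values summed to between 17256903 and 21506481 per library. Depth in reads is unknown, so no counting intervals are given.

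The table held 56299 entries. The 3473 without a gene name and the 3677 that shared a symbol with another were left out, which left 49149 genes. Entries with a mean under 0, of which there were 12672, held continuous noise with a mean of -0.19 and an SD of 1.00, and their 99.9th percentile was 2.81. A floor of 3 was therefore taken as the limit of detection. Genes above 3 in at least 4 libraries were tested, 21566 in all. Where the lower group of a comparison held libraries under the floor, their values were raised to 3 before its mean was taken, and the resulting change is given as a bound. Among the genes kept, 26 had symbols made of digits only, 22 of them tested, and none of these was named. No pair of libraries held identical values.

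The deposited log2 values went into limma 3.58.1 under R 4.3.3 without further scaling. The 4 groups were fitted together with a mean each, the spread was moderated with a trend on expression, and p was adjusted by the Benjamini-Hochberg method over all genes tested. Genes with an adjusted p under 0.05 are called. Tests were two-sided. Models for raw counts were not used, since the table holds none. In data simulated without a group difference, 200 genes were given a change of 0.5 or 1.0 in either direction. Of those changed by 1.0, 73% were recovered in the layout of NKX3.1 against Vector, 67% for R52C against Vector and 75% for NKX3.1 against R52C. Of those changed by 0.5 the percentages were 52%, 66% and 55%. False calls made up 3.85%, 5.67% and 4.41% of calls there.

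Before the data were examined, the tests, the alternatives and 32 gene lists were fixed. The lists were mtDNA-encoded respiratory chain, complex I, complexes II and III, complex IV and ATP synthase (the last 4 nuclear-encoded), mitochondrial chaperones and import, mitochondrial DNA maintenance and transcription, mitochondrial ribosome, NRF2 targets, reactive oxygen detoxification, integrated stress response, endoplasmic reticulum stress, heat shock response, p53 targets, S phase, G2 and mitosis, replication-dependent histones, cytosolic ribosomal proteins, glycolysis, hypoxia response, tricarboxylic acid cycle, cholesterol synthesis, interferon response, inflammatory cytokines and NF-kB targets, prostate luminal and androgen-regulated, basal epithelium, squamous differentiation, neuroendocrine, mesenchymal transition, epithelial adhesion, fibroblast and endothelial, and immune cells. Of their 682 genes, 679 were in the table. Only NDRG1 stood in a pair of lists, hypoxia response and prostate luminal. Each list was tested against the other genes with camera, a set test of limma, at a preset correlation of 0.01 between genes, with adjustment over the 32 lists of a comparison. The same test was run with the correlation estimated per list.

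Genes were named by a rule fixed at the same time. Among called genes whose libraries did not overlap between the groups, with a mean above the median of tested genes and a regular gene symbol, the 10 largest rises and the 10 largest falls were taken in each of the 3 comparisons among Vector, NKX3.1 and R52C. For each comparison with T164A, 5 each way were taken. Of each list described, up to 4 members with the smallest p were added, as were the 13 mtDNA-encoded genes in every comparison. Some genes chosen for testing are not reported here.

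After the data were examined, the share of each library's RNA that matched the R52C libraries was estimated. It rests on 84 genes with a mean of at least 8 in R52C and under the floor in T164A, so that neither Vector nor NKX3.1 entered the choice. For each library the 84 ratios to the mean of R52C replicates 4 to 6 on the linear scale were taken. The peak of their density is called the R52C-like share. It was 96.7% to 97.5% in R52C replicates 1 to 3, which were left out of that reference, and 99.6% to 100.4% in replicates 4 to 6. Where the R52C profile was subtracted, it was the mean of replicates 4 to 6 as well. The median of the ratios was the estimate used first.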

Results

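RNA was measured in 22 libraries titled as RWPE1, an immortalized human prostate epithelial cell line, although markers given below put this in question for some groups. Per the labels, the cells carried an empty vector (Vector, 6 libraries), wild-type NKX3.1 (6), the NKX3.1 form R52C (6) or the form T164A (4). NKX3.1 is a homeodomain transcription factor of the prostate luminal epithelium. All libraries were titled as treated with paraquat, a compound that generates superoxide through redox cycling, and 3 of the 4 T164A libraries lacked the treatment tag. No untreated library was in the series, so an effect of paraquat could not be measured. By its title the series concerns NKX3.1 in mitochondria. The labels do not say whether the libraries of a group came from separate cultures, so the p-values measure only the spread between these libraries, which may be technical. At log2 levels of 8 to 10 the median SD within a group was 0.106 in Vector, 0.0766 in NKX3.1, 0.0681 in R52C and 0.0641 in T164A. Levels are given on the deposited log2 scale as mean ± SD.

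Cell type markers differed between the groups as labelled. KRT5, the basal keratin, was at 16.90 in Vector, 16.53 in NKX3.1, 4.09 in R52C and 15.49 in T164A. TP63, the basal transcription factor, was at 12.36, 11.99, 1.26 and 11.12 in the same order. KLK3, which encodes prostate-specific antigen, was at 12.79, 14.84, 16.58 and 0.26. IRS4, an insulin receptor substrate, was at 13.64 in T164A and under the floor of 3 on average in the other groups. TP63 and IRS4 were chosen after their values were seen.

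**Figure D1:**
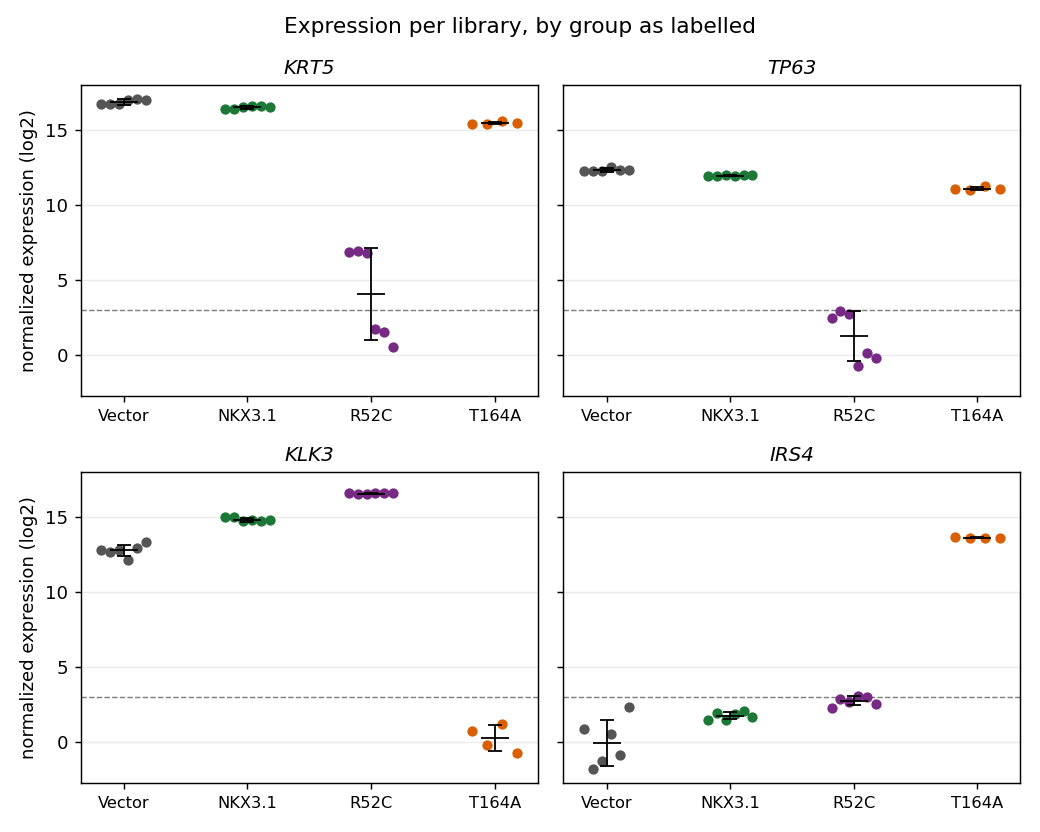
Normalized expression (log2, vertical axis) of KRT5, TP63, KLK3 and IRS4 in each library (points) of the 4 groups as labelled, with mean and SD (black bars) and the floor of 3 (dashed line). KRT5 averaged 4.09 in R52C against 16.90 in Vector.

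NKX3.1 against Vector asks what wild-type NKX3.1 changes in these cells. The largest rises were all about 4-fold. TMEFF2, a transmembrane protein of prostate epithelium, rose by 2.11 (SE 0.14, adjusted p = 1.66e-12), from 6.38 ± 0.47 in Vector to 8.495 ± 0.15 in NKX3.1 (n = 6 each). KLK3 rose by 2.05 (SE 0.20, adjusted p = 4.09e-09). Another 7 of the largest rises lay between 2.01 and 2.09: KLK4, a kallikrein, KIF1A, a kinesin, SPDEF, a luminal transcription factor, the cancer-testis gene MAGEA6, SLC22A31, HPN, a serine protease, and PLEKHB1. Falls were smaller. H19, an imprinted non-coding RNA, fell by 0.85 (SE 0.25, adjusted p = 0.00696). The immediate early genes EGR1 and FOS fell by 0.80 (adjusted p = 0.000434) and 0.76 (adjusted p = 0.000183). CEBPB, a stress-responsive transcription factor, fell by 0.72 (SE 0.07, adjusted p = 8.46e-09). MSLN, WNT10A, COL4A2, HTRA1, PER1 and SLC47A2, the others of the largest falls, changed by -0.80 to -0.67. In each of these genes the 6 NKX3.1 libraries lay apart from the 6 Vector libraries, which the rule for naming genes required.

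The R52C-like share of RNA moved with these groups. It was 5.05% to 10.5% in the Vector libraries and 25.2% to 31.6% in the NKX3.1 libraries. Of the 84 genes it rests on, 61 were higher in every NKX3.1 library than in every Vector library. Across the comparison 8815 of 21566 genes were called, 4636 higher and 4179 lower. At least a doubling was seen for 1126 and at least a halving for 25. In 5141 genes the groups did not overlap, where chance gives 0.216%. With the R52C profile subtracted from each library in that share, 14196 genes could be tested. In those, 5225 were called before, 755 higher and 4470 lower, and 1268 after, 228 higher and 1040 lower, and 750 were called in the same direction both times. With every library shifted to the same median, 35.5% of the called genes were higher in place of 52.6%.

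Of the 32 lists, 12 differed from other genes, and 1 of these held with an estimated correlation. Among 19 prostate luminal genes 14 rose and 2 fell (14 and 2 adjusted over the list alone), with a median change of 1.75 (adjusted p = 1.07e-06, adjusted p = 0.0746 with an estimated correlation). The examples were STEAP2 at 1.84, FOLH1, the prostate-specific membrane antigen, at 1.97 and HOXB13, a prostate homeobox factor, at 1.97. Endoplasmic reticulum stress was the list that held: 12 of 15 genes rose and 0 fell (13 and 0 adjusted over the list alone), with a median of 0.26 (adjusted p = 6.05e-07, adjusted p = 0.028 with an estimated correlation). The chaperones CALR, PDIA4 and HSP90B1 rose by 0.67, 0.80 and 0.56, and the secreted survival factor MANF by 0.95. A sum of Vector and R52C profiles (see Other observations) predicted a median of 0.18 for 14 genes of this list, against 0.25 observed. Of 24 interferon response genes 1 rose and 17 fell (1 and 20 adjusted over the list alone), with a median of -0.30 (adjusted p = 3.88e-05, adjusted p = 0.0746 with an estimated correlation). OAS3 fell by 0.20, IRF7 by 0.42, IFIT1 by 0.44 and DDX58 by 0.33. Of 18 basal epithelium genes 1 rose and 6 fell (the same counts adjusted over the list alone), with a median of -0.37 (adjusted p = 0.0116, adjusted p = 0.586 with an estimated correlation), among them the integrins ITGA3 at -0.40, ITGB4 at -0.39 and ITGA6 at -0.29, and the linker DST at -0.33. The sum of profiles predicted medians of 1.73 for 17 luminal, -0.29 for 13 interferon and -0.36 for 17 basal genes. Those observed were 1.82, -0.30 and -0.38, near the prediction. Genes from which the amounts in the sum were taken were not left out of these lists.

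Lists of oxidative stress and mitochondrial function moved by smaller amounts. The same sum of profiles predicted medians of 0.31 for 21 detoxification, 0.21 for 36 complex I and 0.19 for 15 ATP synthase genes. Those observed were 0.25, 0.15 and 0.10, so the rises did not exceed the prediction. For 24 integrated stress response genes the predicted median was -0.12 and the observed -0.10. Of 26 genes for reactive oxygen detoxification 12 rose and 5 fell (12 and 6 adjusted over the list alone, median 0.10, adjusted p = 0.0116, adjusted p = 0.462 with an estimated correlation). The glutathione transferase GSTM3 rose by 1.43, the peroxiredoxins PRDX2 and PRDX4 by 0.82 and 0.61, and CAT, catalase, by 0.56. Nuclear complex I had 19 genes up and 5 down of 38 (21 and 5 adjusted over the list alone, median 0.14, adjusted p = 0.0116, adjusted p = 0.574 with an estimated correlation), with NDUFA7 at 0.71, NDUFB10 at 0.54 and NDUFB4 at 0.38. Nuclear ATP synthase had 6 up and 1 down of 15 (7 and 1 adjusted over the list alone, adjusted p = 0.0407, adjusted p = 0.630 with an estimated correlation). The tricarboxylic acid cycle had 10 up and 3 down of 16 (the same adjusted over the list alone, adjusted p = 0.0315, adjusted p = 0.574 with an estimated correlation), and glycolysis 11 up and 5 down of 18 (the same adjusted over the list alone, adjusted p = 0.0315, adjusted p = 0.652 with an estimated correlation). Of 25 integrated stress response genes 5 rose and 14 fell (the same adjusted over the list alone, median -0.08, adjusted p = 0.0476, adjusted p = 0.586 with an estimated correlation), with CEBPB at -0.72, the amino acid transporter subunit SLC3A2 at -0.45, CEBPG at -0.24 and NUPR1 at 0.34. Inflammatory cytokines and NF-kB targets had 6 of 16 genes down (6 adjusted over the list alone, adjusted p = 0.0116, adjusted p = 0.284 with an estimated correlation). Mesenchymal transition had 3 of 17 down (3 adjusted over the list alone, adjusted p = 0.0315, adjusted p = 0.462 with an estimated correlation). Complex I, ATP synthase, the tricarboxylic acid cycle and glycolysis passed with Vector replicates 1 to 3 and not with 4 to 6, and the reverse held for the integrated stress response, inflammatory and mesenchymal lists. With every library shifted to the same median the adjusted p was 0.0659 for complex I and for glycolysis, 0.134 for ATP synthase and for the tricarboxylic acid cycle and 0.0936 for mesenchymal transition, and with quantile normalization it was 0.441 for the integrated stress response.

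The other 20 lists did not pass. Their counts, up and down over all genes, were 7 and 1 of 14 for complexes II and III, 6 and 1 of 18 for complex IV, 9 and 5 of 23 for mitochondrial chaperones and import, 4 and 9 of 18 for mitochondrial DNA maintenance and transcription, and 11 and 7 of 39 for the mitochondrial ribosome. They were 12 and 5 of 28 for NRF2 targets, 4 and 4 of 12 for the heat shock response, 6 and 11 of 24 for p53 targets, 3 and 11 of 24 for S phase, and 7 and 1 of 25 for G2 and mitosis. They were 5 and 0 of 14 for replication-dependent histones, 17 and 8 of 60 for cytosolic ribosomal proteins, 8 and 5 of 15 for the hypoxia response, and 7 and 6 of 20 for cholesterol synthesis. Among cell type lists they were 1 and 3 of 19 for squamous differentiation, 1 and 0 of 8 for neuroendocrine genes, 5 and 7 of 15 for epithelial adhesion, 3 and 0 of 8 for fibroblast and endothelial genes, and 0 and 0 of 6 for immune cells. Adjusted over the list alone, the pairs that differed were 7 and 2 for complex IV, 12 and 7 for the mitochondrial ribosome, 4 and 5 for the heat shock response, 6 and 12 for p53 targets, 4 and 12 for S phase, 17 and 9 for cytosolic ribosomal proteins, and 6 and 7 for epithelial adhesion. The median, mean and test of a list differed in sign for the mtDNA-encoded, heat shock, neuroendocrine, epithelial adhesion and immune lists.

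Transcripts of the mitochondrial genome as a list did not differ from other genes (adjusted p = 0.754, median 0.006). Of the 13 genes, 2 rose and 2 fell (the same adjusted over the list alone). MT-ND5 rose by 0.18 (SE 0.04, adjusted p = 0.000309) and MT-ND4L by 0.15 (adjusted p = 0.00169). MT-ND3 fell by 0.22 (SE 0.05, adjusted p = 0.000502), though with quantile normalization its change was 0.02, and MT-CO2 fell by 0.17 (adjusted p = 0.00784). The other 9 genes had changes between -0.11 and 0.07 and did not pass. Transcripts of the mitochondrial genome made up 15.03% to 16.9% of the summed signal in Vector, 14.2% to 16.2% in NKX3.1, 6.12% to 6.66% in R52C and 7.59% to 7.77% in T164A.

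**Figure D2:**
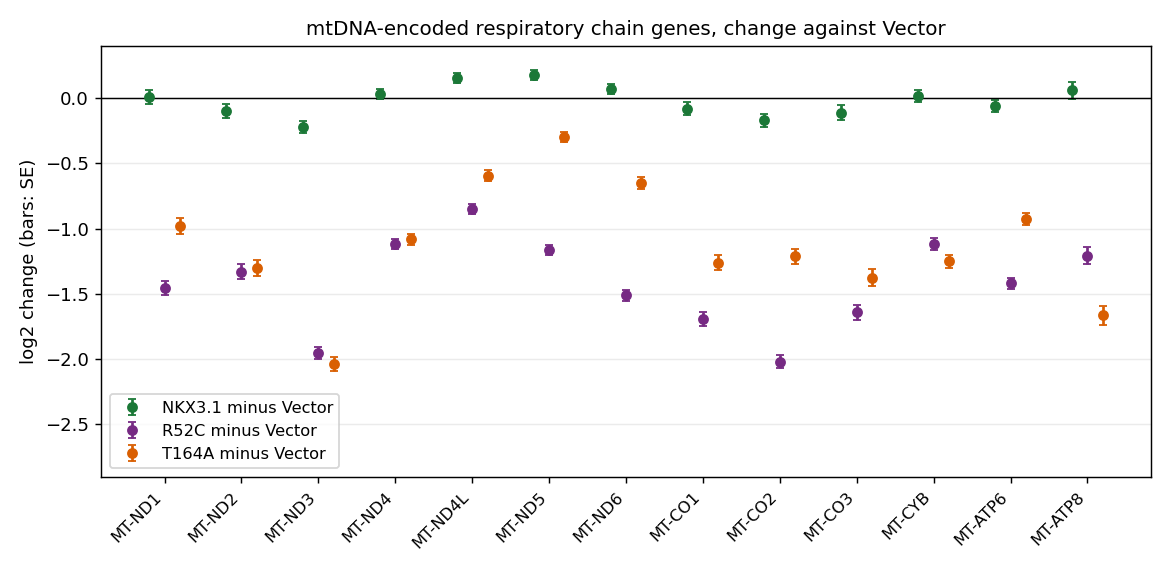
Change against Vector (log2, vertical axis) of the 13 mtDNA-encoded genes in NKX3.1, R52C and T164A, with the standard error of the fit as bars. In NKX3.1 the changes lay between -0.22 and 0.18, while all 13 fell in R52C (-2.02 to -0.85) and in T164A (-2.04 to -0.30), except that quantile normalization gave 0.32 for MT-ND4 in R52C and 0.31 for MT-ND5 in T164A and 0.02 for MT-ND3 in NKX3.1.

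R52C against Vector asks what the R52C form changes, but basal markers such as KRT5 and TP63 were near or under the floor in R52C. Whether these libraries hold the same cells as Vector is in question. A direction drawn from this comparison is therefore one between libraries as labelled. The largest falls were mostly in keratins. KRT5 fell by at least 11.95 (adjusted p = 2.88e-14), from 16.90 ± 0.18 in Vector to 4.09 ± 3.099 in R52C (n = 6 each). The R52C libraries were split in it, with replicates 1 to 3 at 6.85 to 6.95 and replicates 4 to 6 at 0.55 to 1.72. KRT6A fell by at least 11.19 (adjusted p = 3.93e-15). KRT16, KRT17 and KRT1 were at least 1999-fold, 2194-fold and 1511-fold lower, and the desmosomal cadherin DSG3 at least 878-fold lower. GSTP1, a glutathione transferase, was at least 911-fold lower, KRT7 at least 800-fold, KRT4 at least 505-fold and CLCA2 at least 486-fold. LCP1, an actin-bundling protein, rose by 4.20 (SE 0.10, adjusted p = 1.79e-23). TMEFF2, KLK4, MAGEA12, PLEKHB1, MAGEA6, ALOX15 and MAGEA3 rose by 4.08 to 4.16.

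Of 18 basal epithelium genes 17 fell and 1 rose (the same adjusted over the list alone), with a median of -9.47, or -8.96 with undetected genes at their bounds (adjusted p = 4.07e-07, adjusted p = 0.26 with an estimated correlation). ITGA3 fell by 5.69, ITGB4 by 7.09, the desmocollin DSC3 by 7.13 and KRT14 by 8.76. Of 19 squamous differentiation genes 18 fell and 1 rose (the same adjusted over the list alone, median -8.96, or -7.30 with bounds, adjusted p = 2.41e-06, adjusted p = 0.176 with an estimated correlation), with KRT10 at -6.80 and the transglutaminase TGM1 at -5.28. Of 19 luminal genes 16 rose and 3 fell (the same adjusted over the list alone, median 3.46, adjusted p = 0.000951, adjusted p = 0.26 with an estimated correlation). STEAP2 rose by 3.66, while KRT19 fell by 6.17 and NDRG1 by 1.91. The interferon response held with an estimated correlation: 23 of 24 genes fell and 1 rose (the same adjusted over the list alone), with a median of -3.41 (adjusted p = 2.48e-08, adjusted p = 0.0187 with an estimated correlation). IFIT1 fell by 5.01, OAS1 by 5.56, IFI44 by 4.88 and OAS3 by 1.89.

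In R52C all 13 mtDNA-encoded genes fell (13 adjusted over the list alone), from -0.85 for MT-ND4L to -2.02 for MT-CO2, except that quantile normalization gave 0.32 for MT-ND4. Their median was -1.42, or -0.53 with quantile normalization (adjusted p = 5.26e-06, adjusted p = 0.294 with an estimated correlation). Of 15 nuclear ATP synthase genes 14 rose and 0 fell (the same adjusted over the list alone, median 0.84, adjusted p = 0.000104, adjusted p = 0.294 with an estimated correlation), with ATP5I at 2.24, ATP5A1 at 1.92, ATP5D at 1.83 and ATP5B at 1.31. Nuclear complex I had 29 genes up and 5 down (the same adjusted over the list alone, adjusted p = 6.23e-05, adjusted p = 0.294 with an estimated correlation). Mitochondrial DNA maintenance and transcription had 7 up and 11 down of 18 (the same adjusted over the list alone, median -0.40) and did not pass (adjusted p = 0.402). Of 21566 genes 18070 were called, 9062 higher and 9008 lower, 4545 of them higher and 5112 lower by at least 2-fold. In 15253 the groups did not overlap. Altogether 19 lists passed, and 1 held with an estimated correlation.

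NKX3.1 against R52C compares the wild-type form with the libraries labelled R52C, with the same limit. The basal and squamous genes stood higher in NKX3.1, KRT5 by at least 11.59 (adjusted p = 7.39e-14) and KRT6A by at least 10.87 (adjusted p = 9.80e-15). KRT16 was at least 1672-fold higher, KRT17 at least 1430-fold, KRT1 at least 1234-fold and DSG3 at least 783-fold. S100A8, SPINK5, CLCA2 and KRT4 were higher by at least 9.65, 9.14, 8.89 and 8.64. The largest falls lay close together. GUCY1A3, a guanylate cyclase subunit, had a change of -2.22 (SE 0.09, adjusted p = 1.76e-18), and LCP1, WDR72, PRKACB, ALOX15, PRUNE2, ETV1 and LIN7A had changes of -2.21 to -2.12. Of 18 basal genes 17 were higher and 1 lower (the same adjusted over the list alone, adjusted p = 3.03e-08, adjusted p = 0.228 with an estimated correlation). Of 19 luminal genes 3 were higher and 16 lower (the same adjusted over the list alone, median -1.70, adjusted p = 0.00395, adjusted p = 0.241 with an estimated correlation). Of 24 interferon genes 23 were higher and 1 lower (the same adjusted over the list alone), with a median of 3.11 (adjusted p = 3.28e-09, adjusted p = 0.0117 with an estimated correlation). All 13 mtDNA-encoded genes were higher in NKX3.1, by 1.003 to 1.85 (adjusted p = 4.97e-07, adjusted p = 0.241 with an estimated correlation), except that quantile normalization gave -0.32 for MT-ND4. In total 17276 genes were called, 8489 higher and 8787 lower, and 14774 did not overlap. Of the lists 19 passed, 1 of them with an estimated correlation.

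The changes in NKX3.1 and in R52C, both measured against the same Vector libraries, ran in the same direction. Across genes the log2 changes had a Pearson r of 0.69 and a Spearman rho of 0.83, and genes are not independent replicates. In 100 simulations of unchanged groups against the same controls the median r was 0.50 and the highest 0.53. The covariance was 0.670, against 0.0243 in the simulations. With the Vector libraries split between the comparisons, r was 0.56 to 0.64. There were 4581 genes higher in both, 3856 lower in both and 125 called in opposite directions. These counts do not allow for the shared Vector libraries. Nor do they allow for the R52C-like share, which was larger in the NKX3.1 than in the Vector libraries. A larger share alone would move NKX3.1 in the direction of R52C. The agreement therefore cannot be read as a response that both forms of NKX3.1 share.

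**Figure D3:**
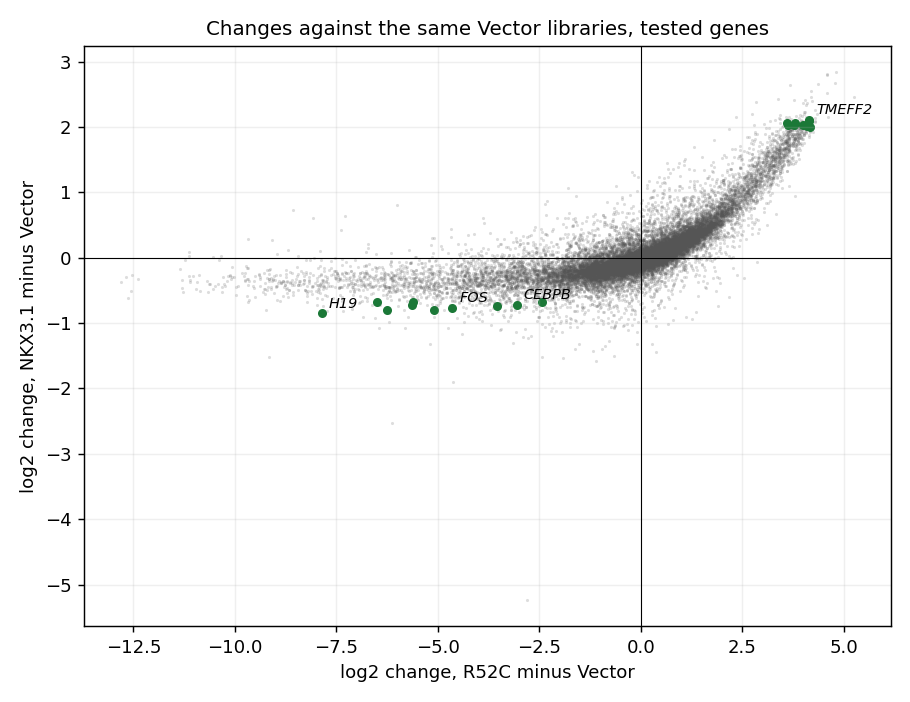
Change of each tested gene in NKX3.1 (vertical axis) and in R52C (horizontal axis), both as log2 difference from the same Vector libraries. Green points are the genes named by rule for NKX3.1 against Vector, of which TMEFF2, H19, CEBPB and FOS are labelled, and 4581 genes were higher in both comparisons.

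T164A against Vector asks what the T164A form changes, but the libraries labelled T164A held genes, such as IRS4, that were under the floor on average in the other groups, so a direction drawn from this comparison is one between libraries as labelled. AMOT, an angiomotin of the Hippo pathway, rose by 7.58 (SE 0.11, adjusted p = 1.98e-27), from 6.62 ± 0.28 in Vector (n = 6) to 14.21 ± 0.02 in the libraries labelled T164A (n = 4). VIM, the mesenchymal filament vimentin, rose by 4.77, ENPP1 by 4.74, SMO, the Hedgehog signal transducer, by 4.52 and ANXA6 by 4.45. KLK3 was at least 883-fold lower, TMPRSS2, an androgen-regulated protease, at least 278-fold, the pseudogene HSPB1P2 at least 226-fold and the imprinted gene PEG3 at least 220-fold. KRT1 fell by 10.35 (SE 0.89, adjusted p = 3.64e-11).

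Mitotic genes rose in the libraries labelled T164A, and epithelial adhesion genes fell. All 25 genes of G2 and mitosis rose (25 adjusted over the list alone), with a median of 1.08 (adjusted p = 1.27e-10, adjusted p = 0.0125 with an estimated correlation). BIRC5 rose by 2.58, CDC20 by 2.19, PLK1 by 2.06 and BUB1 by 1.87. All 15 epithelial adhesion genes fell (15 adjusted over the list alone), with a median of -1.75 (adjusted p = 9.75e-09, adjusted p = 0.00228 with an estimated correlation). DSP, desmoplakin, fell by 2.84, the splicing regulator ESRP1 by 2.27, CDH1, E-cadherin, by 2.03 and GRHL2 by 1.85. Of 24 interferon genes 21 fell and 2 rose (the same adjusted over the list alone, median -2.36, adjusted p = 1.03e-07, adjusted p = 0.0125 with an estimated correlation), with OAS1 at -4.38 and IFI6 at -3.60. Of 19 luminal genes 15 fell and 3 rose (the same adjusted over the list alone, adjusted p = 1.26e-05, adjusted p = 0.116 with an estimated correlation), FOLH1 by 6.79. All 19 squamous differentiation genes fell (19 adjusted over the list alone, median -5.29, or -5.17 with bounds, adjusted p = 8.52e-07, adjusted p = 0.142 with an estimated correlation). All 13 mtDNA-encoded genes fell (13 adjusted over the list alone), from -0.30 for MT-ND5 to -2.04 for MT-ND3, except that quantile normalization gave 0.31 for MT-ND5 (adjusted p = 3.49e-06, adjusted p = 0.213 with an estimated correlation). There were 17711 called genes, 8714 higher and 8997 lower, and 15317 did not overlap, where chance gives 0.952%. Of the lists 20 passed, 3 of them with an estimated correlation.

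**Figure D4:**
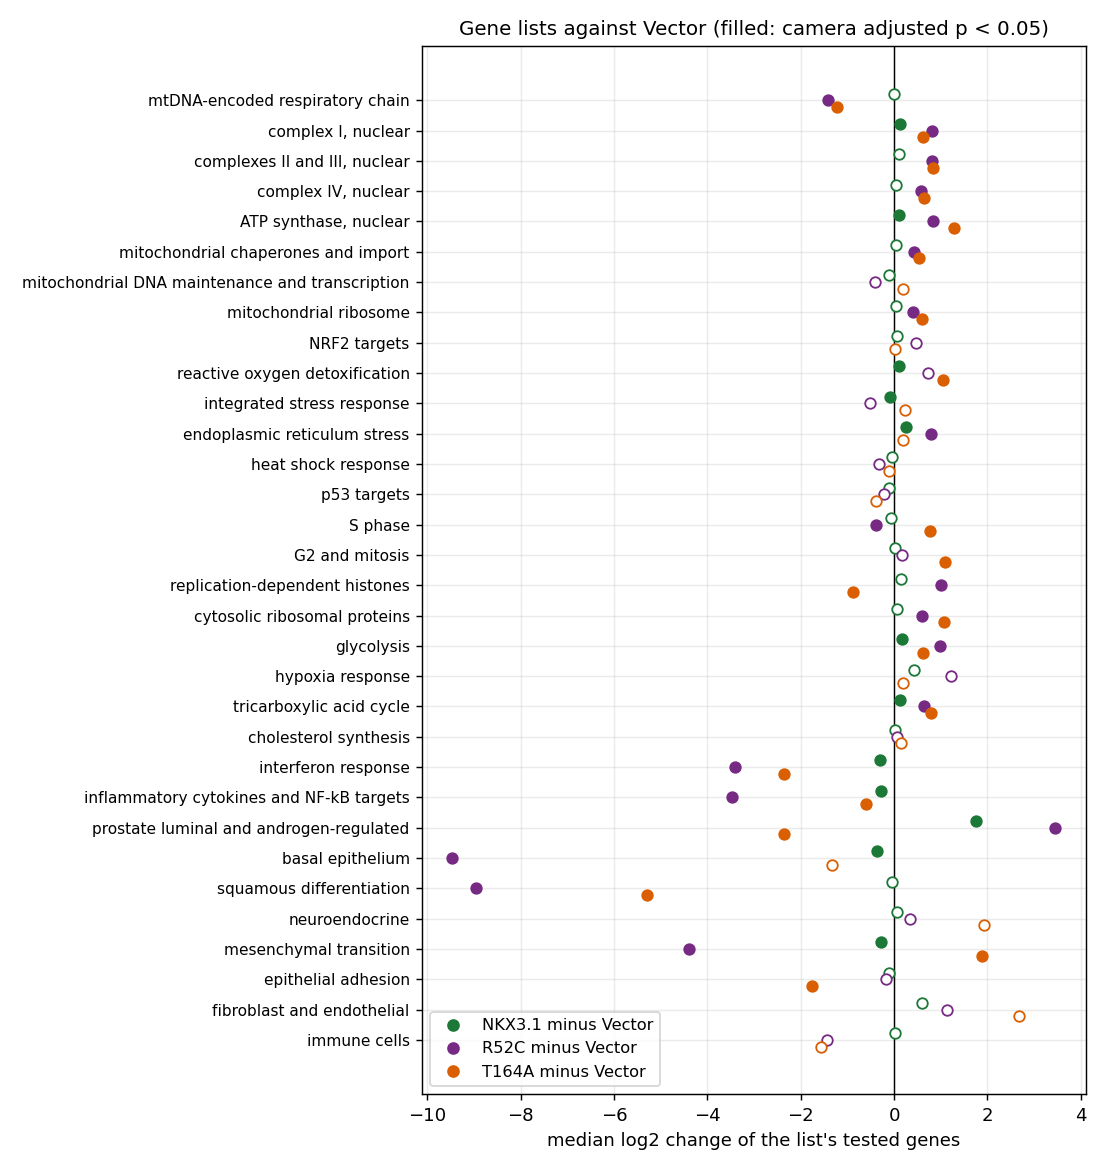
Median log2 change of each of the 32 gene lists (horizontal axis) in NKX3.1, R52C and T164A, each against Vector, with filled points where the camera test at the preset correlation had an adjusted p under 0.05. The luminal list lay at 1.75 in NKX3.1, 3.46 in R52C and -2.36 in T164A.

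NKX3.1 against T164A compares the wild-type form with the libraries labelled T164A. KLK3 was at least 3667-fold higher, TMPRSS2 at least 1097-fold, PEG3 at least 836-fold, the kallikrein KLK2 at least 489-fold and HPN at least 149-fold. AMOT had a change of -7.26, VIM of -5.30, KCTD12 of -4.05, the microtubule-binding MAPRE2 of -4.04 and ZNF703 of -3.72. With an estimated correlation 5 of the 20 passing lists held. Luminal genes were higher in 16 of 19 and lower in 2 (adjusted p = 0.0459 with an estimated correlation), epithelial adhesion genes higher in 14 of 15 and lower in 0 (adjusted p = 0.0029), and interferon genes higher in 21 of 24 and lower in 3 (adjusted p = 0.0219). S phase genes were lower in 19 of 24 and higher in 2 (adjusted p = 0.0306), and G2 and mitosis genes lower in 25 of 25 (adjusted p = 0.0124). Each of these counts was the same adjusted over the list alone. In all 17627 genes were called, 9123 higher and 8504 lower.

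R52C against T164A compares the altered forms with each other, as the libraries are labelled. KLK3, TMPRSS2, PEG3, KLK2 and HPN were higher in R52C by at least 13.58, 11.92, 11.76, 10.76 and 8.98. GSTP1 was at least 862-fold lower and the fibrillin FBN2 at least 459-fold. KRT5 was at least 1496-fold lower and the hemidesmosomal collagen COL17A1 at least 1513-fold. Luminal genes were higher in 17 of 19 and lower in 2 (the same adjusted over the list alone, adjusted p = 1.77e-06, adjusted p = 0.053 with an estimated correlation). Mesenchymal genes were lower in 16 of 17 and higher in 1 (the same adjusted over the list alone, adjusted p = 1.72e-05, adjusted p = 0.053 with an estimated correlation), with VIM at -5.83 and SNAI2 at -5.88. Of the mtDNA-encoded genes, MT-CYB was higher by 0.13 and MT-ATP8 by 0.45, 8 were lower and 3 did not pass, although with libraries shifted to the same median MT-ND4L was at 0.05 and MT-CO3 at 0.04. Of the lists 12 passed with camera, and 0 with an estimated correlation. In all 18050 genes were called, 8283 higher and 9767 lower. With every library shifted to the same median 57.8% of called genes were higher, in place of 45.9%.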

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

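No test in this part was chosen after its result was seen: in each group of 4 or 6 libraries, the distance of the highest or lowest library from its nearest neighbour was compared with the range of the group at the 95% level of Dixon's test. Of 627 groups of values tested, 26 held such a library, where chance gives 31.35 at 1 in 20. T164A replicate 3 stood apart in 6 of them and Vector replicate 4 in 4. The values tested included the R52C-like share, devised after the data were examined, and genes named by rule from these same data. The chance rate is therefore approximate.

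In Vector replicate 4 the mean of the mtDNA-encoded genes was 17.35, against 17.10 to 17.19 in the other Vector libraries. Their percentage of its signal was 16.9, against 15.03 to 15.7. MT-ND5 was at 17.22 there, against 17.02 to 17.09, and ITGA6 at 14.37, against 14.14 to 14.20. PDIA4 was at 11.15 in Vector replicate 6, against 10.78 to 10.91, and SMO at 4.72 in Vector replicate 2, against 5.56 to 6.04.

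In NKX3.1 replicate 4 the mean of mitochondrial chaperones and import was 10.34, against 10.28 to 10.29 in the other NKX3.1 libraries, that of cytosolic ribosomal proteins 11.90, against 11.76 to 11.81, and KRT6B was at 10.51, against 10.32 to 10.39. NRF2 targets averaged 9.40 in NKX3.1 replicate 2, against 9.47 to 9.51. Fibroblast and endothelial genes averaged 2.85 in NKX3.1 replicate 3, against 3.44 to 3.65, and CEBPB was at 11.10 there, against 10.88 to 10.95. In NKX3.1 replicate 1 MAGEA6 was at 8.60, against 8.24 to 8.37, and MANF at 10.01, against 9.86 to 9.92.

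In R52C replicate 2 the glycolysis genes averaged 12.11, against 12.16 to 12.18 in the other R52C libraries, ATP5D was at 10.26, against 10.50 to 10.62, and NUPR1 at 11.36, against 11.49 to 11.56. The hypoxia response averaged 8.58 in R52C replicate 6, against 8.70 to 8.77, and IFI6 was at 7.32 there, against 7.15 to 7.21. In T164A replicate 3 the basal epithelium genes averaged 12.19, against 12.11 in the others, and the immune cell genes 3.99, against 4.46 to 4.53. In the same library KRT14 was at 14.52, against 14.30 to 14.32, CLDN4 at 7.50, against 7.67 to 7.71, MAGEA12 at 4.71, against 5.31 to 5.33, and SLC22A31 at 7.51, against 7.20 to 7.25. ANXA6 was at 11.83 in T164A replicate 1, against 11.78 in the others.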

How the results depend on the processing

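The alternatives with only part of the Vector or R52C libraries, or with the R52C profile subtracted, were chosen after the data were examined, and all others before. Alternative pseudocounts were not run because the values are already logged. No paired analysis was possible because the labels give no shared replicate numbers. For the named genes, 5673 of 5826 values under an alternative kept their direction and their side of the threshold, 80 lost the call, 29 gained one and 44 reversed. The floor of 3 was the limit set for detection, since depth in reads is unknown.

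With a fold change of at least 1.5 required, 819 genes passed for NKX3.1 against Vector, 11227 for R52C against Vector, 8940 for NKX3.1 against R52C, 10066 for T164A against Vector, 9666 for NKX3.1 against T164A and 11226 for R52C against T164A, since this test is stricter by construction. With only the 10783 genes with a mean above the median, the counts were 9933 for R52C against Vector, 9748 for NKX3.1 against R52C, 9612 for T164A against Vector, 9517 for NKX3.1 against T164A and 9670 for R52C against T164A, with fewer genes tested. With an estimated correlation 1 list passed for NKX3.1 against Vector, 1 for R52C against Vector, 1 for NKX3.1 against R52C, 3 for T164A against Vector, 5 for NKX3.1 against T164A and 0 for R52C against T164A. Fewer genes passed for NKX3.1 against Vector with the R52C profile subtracted, 1268, or 1193 with the median share, 264 higher and 929 lower of 13616 tested. With the Vector libraries split, the lowest r between the NKX3.1 and R52C changes was 0.56.

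Shifting the libraries to the same median moved the median change of all genes to -0.10 for NKX3.1 against Vector, 0.14 for R52C against Vector, -0.25 for NKX3.1 against R52C, -0.21 for T164A against Vector, 0.15 for NKX3.1 against T164A and 0.21 for R52C against T164A. Quantile normalization moved it to 0.19 for R52C against Vector, -0.27 for NKX3.1 against R52C and 0.11 for R52C against T164A. Changes smaller than these depend on the scaling.

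Leaving out 1 library at a time gave 8172 to 8631 genes for NKX3.1 against Vector, 17890 to 18013 for R52C against Vector, 17003 to 17084 for NKX3.1 against R52C, 17282 to 17720 for T164A against Vector, 17155 to 17468 for NKX3.1 against T164A and 17713 to 17908 for R52C against T164A. Lists passing numbered 9 (without Vector replicate 1) to 13 (without Vector replicate 5), 19, 19, 20, 19 to 20 and 12 in the same order.

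The reversed values are log2 changes, and the cause was not tested for any of them. For NKX3.1 against Vector with libraries shifted to the same median, MT-ND1 was at -0.0783, MT-ND4 at -0.0538, MT-ND6 at -0.0143, MT-CYB at -0.066 and MT-ATP8 at -0.022, and with quantile normalization MT-ND3 was at 0.018. Leaving out 1 library, MT-ND1 ranged from -0.0222 (without Vector replicate 1) to 0.0543 (without Vector replicate 4) and was reversed without Vector replicate 1, 2 or 3 or NKX3.1 replicate 3, 4 or 6, and MT-CYB ranged from -0.00862 (without Vector replicate 1, reversed) to 0.0534 (without Vector replicate 4). With Vector replicates 1 to 3 only, MT-CO1 was at 0.00591, and with replicates 4 to 6 only MT-ND1 was at -0.11, MT-ND6 at -0.019 and MT-CYB at -0.0737. With the R52C profile subtracted, MT-ND2 was at 0.12, MT-ND3 at 0.0374, MT-CO1 at 0.17, MT-CO2 at 0.0942, MT-CO3 at 0.13, MT-ATP6 at 0.17, OAS3 at 0.0618 and ITGA6 at 0.0419. With the median share these were 0.13, 0.0519, 0.19, 0.11, 0.14, 0.18, 0.0765 and 0.0599, and DST was at 0.0105. With quantile normalization MT-ND4 was at 0.32 for R52C against Vector, -0.32 for NKX3.1 against R52C and 0.86 for R52C against T164A, and MT-ND5 at 0.31 for T164A against Vector and -0.19 for NKX3.1 against T164A. For R52C against T164A with libraries shifted to the same median, MT-ND2 was at 0.28, MT-ND4 at 0.27, MT-ND4L at 0.0496 and MT-CO3 at 0.0409, and with R52C replicates 4 to 6 only MT-ND2 was at 0.00496.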

Other observations

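The tests on the rise of luminal genes and on the mtDNA-encoded genes were chosen after the results they bear on were seen. The tests on the R52C and T164A libraries, and the counts of other splits, were set before. All genes in this part other than the mtDNA-encoded genes were chosen after their values were seen, except those named in the lists of 4 below.

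The R52C profile was subtracted from the Vector and NKX3.1 libraries. CEBPD, a transcription factor of the C/EBP family, then had a change of -0.85 (SE 0.16; adjusted p = 0.00404), against -0.81 before, at -0.41 against Vector replicates 1 to 3 and -1.28 against replicates 4 to 6. CEBPB of the same family had a change of -0.44 (SE 0.05; adjusted p = 0.000166), against -0.72 before, at -0.33 and -0.55 against the same sets. The epithelial protease inhibitors PI3 and SPINK5 had changes of 0.64 (adjusted p = 0.0145) and 0.45 (adjusted p = 0.0117), against 0.28 and 0.09 before, at 0.16 and 0.13 against Vector replicates 1 to 3 and 1.13 and 0.77 against replicates 4 to 6. Of 13 mtDNA-encoded genes 7 rose, with a median of 0.23, and of 18 squamous differentiation genes 8 rose, with a median of 0.26. Of 32 cytosolic ribosomal protein genes 11 fell, with a median of -0.18. The interferon and basal lists had medians of 0.008 and -0.02. How far these list medians depend on either set of Vector replicates was not computed. Against Vector replicates 1 to 3 alone 784 genes passed, against replicates 4 to 6 alone 3853, and 392 passed in the same direction with both.

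The lists of NRF2 and p53 targets passed in none of the 6 comparisons. Of single stress genes, GDF15, a stress-induced cytokine, averaged 11.75 in Vector, 13.17 in NKX3.1, 14.45 in R52C and 8.68 in T164A. CDKN1A, the p21 inhibitor of the cell cycle, averaged 13.81, 13.46, 11.62 and 10.95 in the same order. HMOX1, heme oxygenase, averaged 6.24, 6.45, 7.09 and 8.20, NQO1, a quinone reductase, 9.88, 9.86, 10.49 and 10.01, and SOD2, the mitochondrial superoxide dismutase, 10.36, 10.24, 10.30 and 11.16. The libraries labelled T164A also held LIN28B, an RNA-binding protein of early development, at 10.43, SALL1, a kidney transcription factor, at 9.48, and the neurofilament genes NEFM and NEFL at 11.23 and 10.65. In Vector these were at 0.85, -0.43, 3.39 and 6.67.

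Luminal genes were higher in NKX3.1 than in Vector libraries by a median of 1.75. The scaling between libraries is argued against, since the median stayed at 1.77 with quantile normalization. An effect of NKX3.1 on the genes of the list and no others is argued against too. The 79 genes chosen on R52C and T164A outside the list had a median change of 1.68. As these were chosen for being high in R52C, they may be luminal genes as well. The test therefore cannot decide on an effect on luminal genes more widely. A larger share of the cells that make up the R52C libraries, with no other cells expressing the chosen genes, is excluded, since it predicted 1 common rise and their 25th to 75th percentile spanned 1.60 (0.35 to 1.95) against a bound of 1. Its successor, used because 23 of the 84 genes stood in Vector at over 25% of their R52C level, took 0.778 of the Vector and 0.204 of the R52C profile, and for 157 other genes with a predicted rise of 1 or more the 25th to 75th percentile of observed minus predicted spanned 0.175 (-0.11 to 0.07), which is consistent with a larger share of such cells. A part of the RWPE1 cells taking on the expression of the R52C libraries cannot be told apart from it, and an effect of NKX3.1 itself remained open as untested.

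The share in that comparison depends on its estimate. By the peak of the ratios its mean was 7.52% in Vector and 27.8% in NKX3.1, and by their median, used first and replaced after its values were seen, 8.65% and 29.6%. Across 9596 other genes, which are not independent replicates, observed and predicted change had a Pearson r of 0.96 and a Spearman rho of 0.91. Both changes are taken against the same Vector mean, which alone gives a positive r, and no simulation allowed for this. For 326 genes high in T164A and undetected in R52C the change predicted from the shares by the peak was -0.36 and the observed median -0.35. The amount of 0.778 of the Vector profile was itself taken from these 326 genes. Among genes that departed from the prediction, CEBPB lay at -0.41, JUNB at -0.32, PRDX3 at -0.26, GDF15 at 0.34 and LAMB2 at 0.33.

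In the R52C libraries basal genes were lower than in Vector by a median of 9.47, or 8.96 with bounds, while luminal genes were higher by a median of 3.46. A candidate explanation is cells of the LNCaP prostate line in place of RWPE1 cells, which was tested on properties of that line. That for JAK1 was met, at 7.53 in R52C against 11.12 in Vector. UGT2B15 and UGT2B17, at 6.50 and 6.97, did not reach the 8 that was set, though they were at 3.40 and 3.90 in Vector. The test left this explanation undecided, and an effect of the R52C form remained open as untested.

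In the libraries labelled T164A IRS4, LIN28B and SALL1 were high. Cells of the HEK293 line in these libraries were tested on 4 genes that this line is known to express, of which 3 were met: INA at 7.96, CDH2 at 10.48 and EYA1 at 6.11, against 5.92, 4.93 and 2.43 in Vector. NEFH, at 2.99 against 2.82, was not. Of the 4, INA and CDH2 were above the floor in Vector as well, and KRT5 was at 15.49 in T164A, so the values are consistent with such cells as a part of these libraries but not with these cells alone. An effect of the T164A form, which the labels would give, remained open as untested.

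NKX3.1 raising mtDNA-encoded transcripts was tested against the level predicted from the Vector and R52C profiles. All 13 genes lay above it, by 0.05 to 0.38 with a median of 0.21, and the median was 0.20 with Vector replicates 1 to 3 and 0.17 with replicates 4 to 6. With replicates 1 to 3 alone MT-ND3 lay below the prediction, at -0.06. Of the 13, 11 exceeded 0.12, the 95th percentile of 4063 genes with a mean above 10. The 13 genes are not independent replicates. The mean of the 13 genes ranged by 0.2503 within the Vector libraries alone, more than that median, and by 0.229 within the NKX3.1 libraries. Without Vector replicate 4 the Vector range was 0.0881, less than that median, so the outcome rests on this library. NKX3.1 may raise these transcripts, but the test did not decide it, and the bound from the Vector range was added after the first form of the test had been met.

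Other splits of the same libraries, 100 drawn for each comparison from 462 possible ones, or 210 with T164A, asked whether chance gives as many called genes. In each comparison 1 of the 100 reached the real count, the real split itself, so chance in how these libraries fell into groups is argued against. If the libraries of a group came from 1 culture, a difference between single cultures cannot be excluded this way. The highest other split called 4288 genes against 8815 for NKX3.1 against Vector, 15289 against 18070 for R52C against Vector, 13915 against 17276 for NKX3.1 against R52C, 14609 against 17711 for T164A against Vector, 13789 against 17627 for NKX3.1 against T164A and 14871 against 18050 for R52C against T164A. Within Vector, replicates 1 to 3 and 4 to 6 lay apart on the first component, which held 64.4% of the variance there.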
